A study of Mus musculus with 48 samples.

How the data were processed

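RNA from the hippocampus of each mouse was extracted with Trizol, amplified with a Nugen Ovation kit and labelled with Cy3 for NimbleGen arrays, per the labels' protocols. The authors deposited 1 intensity per transcript feature and array on a linear scale, made with RMA, per the submitters' processing notes, which give no version. Which arrays were normalized together is not given in the sources used here. Of 44170 features, 44155 rested on 3 probes and 15 on 1 or 2, per the file headers, and 1 further row of 5000 random control probes gave the chip background. The series value table held the same values, with a largest difference of 0.0.

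Symbols in the files were updated by Entrez identifier to those of the GRCm38.p6 annotation for 39057 features, and by accession for 2. For 2829 features the name in the file was kept, and 2282 had no symbol. Coordinates are those of the files, on mm9. Intensities were log2-transformed with no pseudocount. The 2 arrays of a mouse were averaged, so that n counts mice, and for a gene with several features the brightest by overall mean was used, which applied to 10215 genes. This left 26455 genes, of which 2282 were unnamed features. No filter on dim genes was applied in the main test. Columns of other samples numbered 0.

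Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 24 mice with group and slide pair as terms, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Tests were two-sided. The 4 slides formed 2 pairs, each pair with 4 mice of every group. Columns of the slides followed the groups and cannot be told apart from them. In every group the mice of the first pair were killed at earlier hours than those of the second. Each cage of resting controls lay within a single pair, as did most cages of swum mice. Slide pair, cage and time of sacrifice can therefore not be fully separated. Mean sacrifice time was 13.5 h for resting controls, 14.6 h for swum controls and 15.5 h for the stressed lineage. Cages lay within groups, with 2 for resting controls and 3 for each swum group, and resting and swum controls shared 3 litters. Duplicate arrays of a mouse correlated at 0.797 by duplicateCorrelation.

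The 30 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. The preset and estimated correlations differ most for the choroid plexus markers, whose estimated value was 0.706. Named genes followed a rule fixed at the same time. It took, per comparison, the 10 highest and 10 lowest log2 fold changes among genes that passed and whose brighter group lay above the highest chip background, or the 10 smallest p where fewer than 10 genes passed. List members that passed were added, up to 4 per list, as were 20 genes named in advance, of which Egr1 was not analysed here and 1 other is not reported here. Csrnp1, and in the third comparison Btg2 and Homer1, were named outside that rule.

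The procedure was tested on simulated data with the spread of these arrays, in which 200 genes were changed. For the swim comparison it recovered 46 of 50 genes changed by 1 log2 unit, 25 of 50 changed by 0.5 and 8 of 50 changed by 0.25, with 7 false calls among 135. Alternatives changed the slides, mice, blocks, covariates, scaling, filters, features and thresholds. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.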

Results

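Hippocampal transcripts were measured in 24 C57BL/6J mice on 48 one-colour arrays, with 2 arrays per mouse. The mice formed 3 groups of 8. Resting controls descended from fathers raised with control handling. Swum controls had the same descent and were killed 45 min after a 6 min forced swim in water at 18 °C. Swum stressed-lineage mice went through the same swim, and their fathers had been exposed in early life to maternal separation with unpredictable stress. The protocol in the labels places the resting condition 2 weeks after a swim, whereas the phenotype label of the resting controls names only control handling, so whether these mice had swum earlier is unsettled. Swum and resting mice were killed on different days, so day and swim cannot be told apart. No resting stressed-lineage group was analysed here, and a difference between lineages in the size of the swim response could therefore not be fitted. Chip background lay between 5.07 and 5.26 on the log2 scale, 19510 of the 26455 genes tested averaged at least 1 log2 unit above it, and the number of mice limits the precision.

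The comparison of swum with resting controls asked which hippocampal transcripts differed 45 min after acute stress. The immediate early gene Ccn1, which encodes a secreted matrix protein, was 3.89-fold higher, with log2 intensities of 7.05 ± 0.39 (SD, n = 8) in resting and 9.01 ± 0.55 (SD, n = 8) in swum controls. Fos, a subunit of the AP-1 transcription factor, was 2.43-fold higher, at 9.21 ± 0.09 against 10.50 ± 0.25 (SD, n = 8 each), and Apold1, an early response gene of endothelial cells, was 2.20-fold higher, at 12.70 ± 0.11 against 13.84 ± 0.04 (SD, n = 8 each). Dusp1, a phosphatase that inactivates MAP kinases, was 1.72-fold higher. For each of these genes 8 of 8 swum mice lay above the resting mean, and the limma adjusted p was 3.40e-05 for Ccn1, 2.30e-06 for Fos, 3.09e-11 for Apold1 and 1.43e-06 for Dusp1. In the second slide pair alone Apold1 passed, whereas Ccn1, Fos and Dusp1, at log2 fold changes of 1.92, 1.29 and 0.74, had adjusted p of 0.430, 0.186 and 0.186. In all, 80 of 26455 genes passed, of which 48 rose and 32 fell. Without mouse 64, 49 rose and 53 fell. On mm9 coordinates the transcripts lie on chromosome 3 from 145309939 to 145312929 for Ccn1, on chromosome 12 from 86814850 to 86818219 for Fos, on chromosome 6 from 134932018 to 134936854 for Apold1 and on chromosome 17 from 26642535 to 26645404 for Dusp1.

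**Figure D1:**
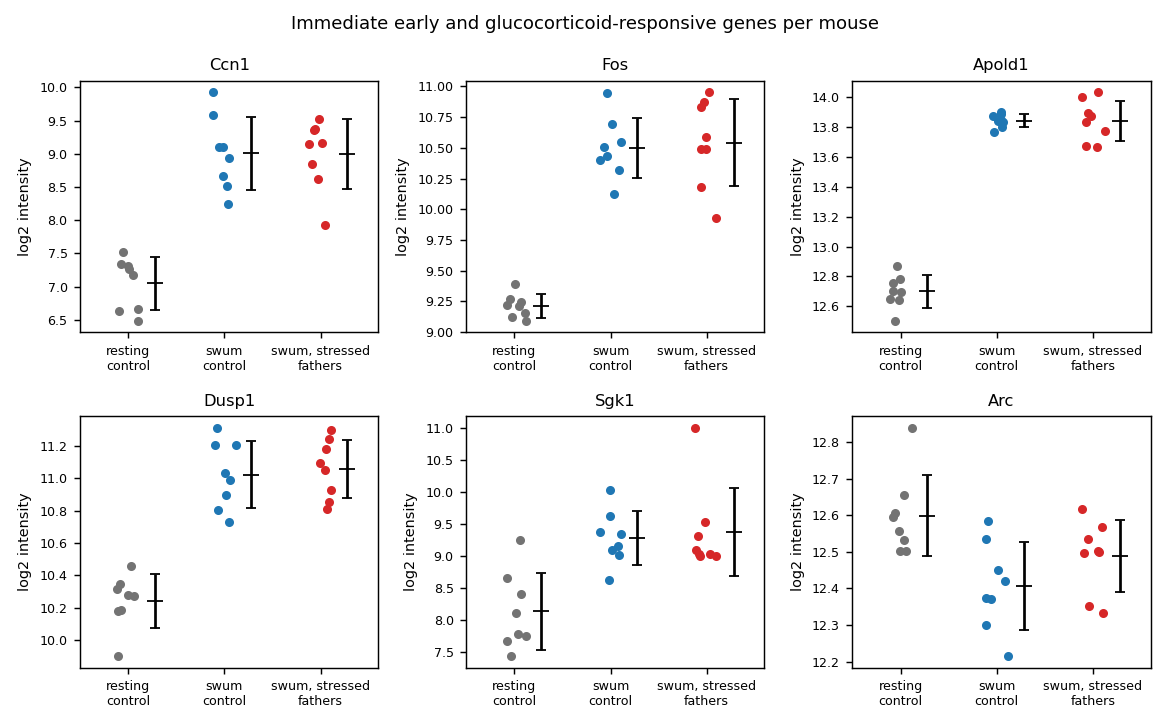
Log2 array intensity of 6 genes in each of the 24 mice (points, mean of 2 arrays), with the group mean and SD beside them. For Ccn1, Fos, Apold1 and Dusp1 every swum mouse lies above every resting mouse, whereas Sgk1 overlaps between groups and Arc, at 12.60 in resting and 12.41 in swum controls, did not pass the test.

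Of 33 measured immediate early genes, 7 rose and 0 fell, or 11 rose and 1 fell when adjusted over the list alone. Besides Ccn1, Fos, Apold1 and Dusp1 these were Maff, a small Maf transcription factor, at a log2 fold change of 0.89 (SE 0.17), Btg2, an antiproliferative early gene, at 0.87 (SE 0.13), and Csrnp1, a nuclear early response protein, at 0.58 (SE 0.06). Csrnp1 was named after its value was seen. The list as a whole shifted upward by camera with an adjusted p of 8.76e-15, and adjusted p = 0.0120 with an estimated correlation. Its median log2 fold change was 0.19, with 0.18 in the first slide pair and 0.23 in the second. Other early genes did not pass: Arc, a synaptic plasticity gene, was at -0.19 (adjusted p = 0.147), Junb at 0.19 (adjusted p = 0.696) and Npas4, near background, at -0.11 (adjusted p = 0.823).

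Among named genes outside that list that passed, Cldn20, a tight junction claudin, had the highest log2 fold change, at 1.16 (SE 0.14). Nfe2l2, the NRF2 regulator of oxidative stress genes, followed at 0.99 (SE 0.19), and Zfp36, which promotes mRNA decay, at 0.94 (SE 0.19). The splicing factor gene Srsf10 was next, at 0.92 (SE 0.13). Zfp36 lay above background in 3 of 8 resting and 8 of 8 swum mice, and with background in place of lower values it was at least 0.78 log2 units higher. Another feature of Nfe2l2 had the opposite sign, as did 1 of 3 features of Srsf10. The lowest values were those of Gm10766 at -1.30 (SE 0.28), Gm5782 at -0.96 (SE 0.12), Dnase1l2, a DNase I-like nuclease, at -0.85 (SE 0.11), Cog8, a subunit of a Golgi tethering complex, at -0.78 (SE 0.11), and Gm3354 at -0.73 (SE 0.12). Cbx2, a Polycomb protein, followed at -0.65, Slc35d1, a nucleotide-sugar transporter, at -0.60, Scai at -0.58, Dguok, the mitochondrial deoxyguanosine kinase, at -0.54, and Fndc8 at -0.52. All of these genes passed the test. For Slc35d1 and for Scai, 1 of 3 features had the opposite sign. In 24 fits that each left out 1 mouse, the call ended at least once for Nfe2l2, Zfp36, Gm10766, Cbx2 and Slc35d1, which passed in 21, 17, 7, 14 and 13 of them, and for Maff, Clock and Flt1, which passed in 18, 17 and 17.

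Glucocorticoid-responsive genes gave 1 rise, that of Dusp1, and 0 falls among 27 measured, and 2 rises and 2 falls when adjusted over the list alone. The list showed no shift in a common direction (camera adjusted p = 0.566). Fry without regard to direction gave an adjusted p of 6.83e-04, and 0.585 with direction. Sgk1, a kinase induced by glucocorticoids, was at 1.15 (SE 0.26) and missed the threshold (adjusted p = 0.0585), with 1.64 in the first slide pair and 0.67 in the second. It passed with arrays centred on their medians (adjusted p = 0.0289), with features averaged, where its log2 fold change was 0.40 (adjusted p = 0.0234), without mouse 71, 73, 74 or 81 singly (adjusted p = 0.0428, 0.0341, 0.00964 and 0.0283) and without mice 74 and 81 together (adjusted p = 9.13e-04), and had an adjusted p of 0.518 with cage as a random block, the highest of its alternatives. The glucocorticoid receptor gene Nr3c1 was at 0.39 (adjusted p = 0.0569), the mineralocorticoid receptor gene Nr3c2 at 0.61 (adjusted p = 0.211), the receptor co-chaperone gene Fkbp5 at 0.19 (adjusted p = 0.718) and the clock gene Per1 at 0.14 (adjusted p = 0.520). Per1 passed with features averaged, at 0.59 (adjusted p = 2.03e-04). Nr3c1 passed without mouse 61, 64, 66, 71, 74 or 82 singly (adjusted p = 0.0487, 0.0455, 0.0354, 0.0416, 0.0254 and 0.0425), without mice 74 and 81 together (0.0376), with litter as a random block (0.0448) and with quantile normalization repeated (0.0333), with the highest of its alternatives at 0.536, with features averaged. Nr3c2 passed without mouse 71 (adjusted p = 0.0397). Bdnf was at 0.03, Crh at 0.01, Gria1 at 0.11, Grin1 at 0.14, Dnmt1 at 0.19, Dnmt3a at 0.22 and Cirbp at 0.28, and none of them passed. Without mouse 81 Grin1 was at -0.05, Fkbp5 at 0.11, Npas4 at -0.16 and Bdnf at 0.06, and without mouse 67 Junb was at 0.32, whereas the sign of Crh turned without several single mice.

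Of 3 cold-inducible RNA-binding genes, 1 rose and 0 fell, over all genes and adjusted over the list alone: Srsf5, a splicing factor, at 0.51 (SE 0.08). The list passed camera (adjusted p = 0.00119), and adjusted p = 0.0137 with an estimated correlation. Of 17 circadian clock genes, 1 rose, Clock, at 0.44 (SE 0.09), and 3 when adjusted over the list alone (camera adjusted p = 0.0233, and adjusted p = 0.0700 with an estimated correlation). Of 33 genes for glutamate receptors and the postsynaptic density, 1 rose, the kainate receptor gene Grik1, at 0.53 (SE 0.09), and 2 when adjusted over the list alone (camera adjusted p = 0.00556, and adjusted p = 0.215 with an estimated correlation). Tet3, which oxidises 5-methylcytosine, rose by 0.44 (SE 0.07) as 1 of 30 DNA methylation and histone-modifying genes, and Flt1, a VEGF receptor, rose by 0.48 (SE 0.09) as 1 of 15 endothelial and pericyte markers.

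Markers of the choroid plexus, an epithelium beside the hippocampus, had higher means in swum controls in 18 of 18 cases, with a median log2 fold change of 0.46, of 0.61 in the first slide pair and 0.37 in the second, although 0 passed singly and 0 when adjusted over the list alone. The mean of the markers was 10.93 in mouse 59 and 10.37 in mouse 72, and at most 9.11 in the other swum controls. The list passed camera (adjusted p = 2.14e-07), with adjusted p = 0.313 with an estimated correlation and 0.230 by fry. The thyroxine carrier gene Ttr, abundant in this epithelium, was at 14.21 ± 0.24 in resting and 14.44 ± 0.07 in swum controls (SD, n = 8 each). Its log2 fold change was 0.23 (limma adjusted p = 0.207), and 0.85 with its 2 features averaged (limma adjusted p = 0.217). Of 14 oligodendrocyte markers 0 passed, at a median of 0.09 (camera adjusted p = 0.0133, and adjusted p = 0.291 with an estimated correlation). The other 24 lists did not pass camera, with adjusted p from 0.0870 to 0.953. They covered late activity-regulated, stress-axis, heat shock, GABA, protein kinase C, serotonin and dopamine, respiratory chain, ribosomal and interferon-stimulated genes, and markers of thalamus, cortex and striatum, dentate granule, CA1, CA3 and CA2 cells, interneurons, astrocytes, oligodendrocyte precursors, microglia, leptomeninges, blood and sex-linked genes, besides the glucocorticoid, DNA methylation and endothelial lists above.

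**Figure D2:**
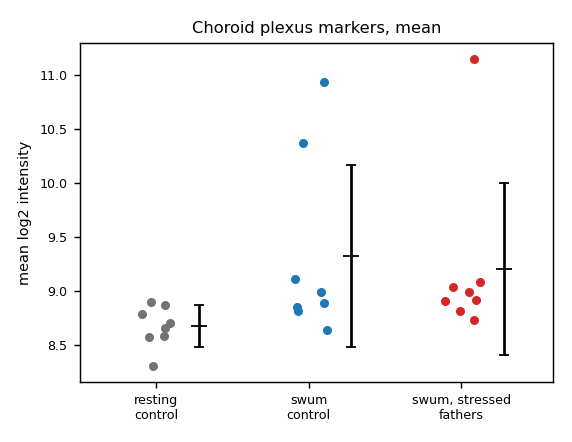
Mean log2 intensity of 18 choroid plexus markers in each of the 24 mice (points), with the group mean and SD beside the points. In the stressed lineage 1 mouse reaches 11.15, and in swum controls 2 mice lie at 10.93 and 10.37, against at most 8.90 in resting controls.

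The count of 80 genes was 173 in the first pair and 1 in the second, 18 with cage as a random block, 37 within the 3 litters that held both groups (4 resting and 7 swum mice), of which 7 were among the 80 and 34 rose and 3 fell, 52 with time of sacrifice as a covariate and 294 without mice 74 and 81, whose arrays correlated least with their groups. With cage as a random block the call ended for Nfe2l2, Zfp36, Maff, Gm10766, Cbx2, Slc35d1, Fndc8, Clock, Srsf5, Grik1, Tet3 and Flt1. Within the shared litters Ccn1, Fos, Apold1, Cldn20 and Srsf10 passed, and the adjusted p of Dusp1 was 0.0590. With features averaged the call ended for Nfe2l2 (0.47), Srsf10 (0.42), Slc35d1 (-0.24), Scai (-0.22), Clock (0.51) and Srsf5 (0.65), and Dguok and Grik1 passed at -0.36 and 0.32. The split into rises and falls was 129 and 44 in the first slide pair, 174 and 65 without mouse 71, and 72 and 27 without mouse 81. The count moved by over 1.5 times without mouse 59 (36), 60 (47), 66 (122), 67 (50), 71 (239), 72 (42), 74 (241), 75 (43), 76 (50), 77 (39), 78 (46) or 79 (47).

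The comparison of the swum groups asked whether paternal early-life stress was accompanied by a different hippocampal profile after the swim. No gene passed: limma called 0 of 26455 genes, with 1844 at an unadjusted p under 0.05 and a smallest adjusted p of 0.654. Fos was at 10.50 ± 0.25 in swum controls and 10.54 ± 0.35 in swum stressed-lineage mice (SD, n = 8 each), a log2 difference of 0.05 with a 95% interval from -0.20 to 0.29 in the limma fit. Dusp1 differed by 0.03, with an interval from -0.11 to 0.18. On simulated data with the spread of these arrays, this comparison recovered 45 of 50 genes changed by 1 log2 unit, 28 of 50 changed by 0.5 and 7 of 50 changed by 0.25. The 200 genes changed in the simulation ease the adjusted threshold, so recovery with fewer changed genes would be lower. In the measured data the largest difference of any gene, 1.40 log2 units, did not pass.

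Of the 10 genes named for the smallest p, none passed, and the 8 with means above background had higher means in the stressed lineage. Tph1, a tryptophan hydroxylase, was at 8.07 ± 0.42 in swum controls and 9.17 ± 0.92 in the stressed lineage (SD, n = 8 each), a log2 difference of 1.10 (SE 0.27), or of 0.68 with features averaged. The differences were 0.58 for Mcub, a subunit of the mitochondrial calcium uniporter, 0.57 for Lhfpl1, 0.50 for Plcz1, 0.50 for Gm2260, 0.48 for Smpdl3b, 0.46 for Fhdc1 and 0.31 for Zfp110. The mean values of Reg2 and Neurod4 lay below background in both groups, and no difference is given for them.

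Sgk1 differed by 0.09, Fkbp5 by -0.31, Nr3c1 by -0.17, Nr3c2 by 0.16, Crh by 0.12, Bdnf by 0.04, Arc by 0.08, Npas4 by 0.19, Junb by 0.09 and Per1 by -0.04, with none passing. The glutamate receptor genes Gria1 and Grin1 were at -0.07 and -0.40, the DNA methyltransferase genes Dnmt1 and Dnmt3a at -0.10 and -0.03, Ttr at -0.02 and Cirbp at 0.13. Ttr was at -0.17 with features averaged. Without mouse 74 Sgk1 was at -0.12, Fkbp5 at -0.14, Grin1 at -0.18, Dnmt1 at 0.03, Junb at -0.01, Nr3c2 at 0.10, Crh at 0.06 and Cirbp at 0.03, and Gria1, Bdnf, Per1 and Dnmt3a lay closer to 0. Sgk1 was at -0.04 without mouse 73, Junb at -0.04 without mouse 67, and Nr3c2 at 0.35, Cirbp at 0.26 and Dnmt3a at 0.03 without mouse 71, and with features averaged Arc was at -0.18, Bdnf at -0.08, Per1 at 0.03 and Dnmt3a at 0.13. No member of any of the 30 lists passed over all genes. By camera, the lists of glutamate receptors and the postsynaptic density (median -0.05, adjusted p = 0.00255), astrocyte markers (median -0.05, adjusted p = 0.0167) and oligodendrocyte markers (median -0.04, adjusted p = 0.0209) lay lower, with adjusted p = 0.242, 0.242 and 0.372 with an estimated correlation. In the first slide pair these medians were 0.00, 0.01 and -0.02, and in the second -0.05, -0.11 and -0.07. Without mice 74 and 81 they were -0.03, -0.02 and -0.05, and the astrocyte list lost its call (camera adjusted p = 0.095). With arrays centred on their medians they were -0.09, -0.09 and -0.08. The lineages shared 0 litters and no cage held both, so paternal stress and litter cannot be told apart.

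The third comparison set swum stressed-lineage mice against resting controls, and so combined lineage and swim. Ccn1 was higher by 1.95 on the log2 scale (SE 0.21), Fos by 1.33 (SE 0.12) and Apold1 by 1.14 (SE 0.06), each in 8 of 8 mice. In the second slide pair alone Apold1 passed, whereas Ccn1 and Fos, at 2.14 and 1.27, had adjusted p of 0.221 and 0.218. Sgk1, on chromosome 10 from 21601989 to 21618949 on mm9, passed here at 1.24 (SE 0.26, limma adjusted p = 0.0229), and at 0.54 with features averaged (adjusted p = 0.00238), but not without mouse 70, 75 or 77 singly (adjusted p = 0.0506, 0.0575 and 0.0574), with cage as a random block (adjusted p = 0.212) or with time of sacrifice (adjusted p = 0.121). In all, 284 genes passed, of which 256 rose and 28 fell. With arrays centred on their medians the split was 171 and 44, with time of sacrifice 34 and 12, without mouse 74 222 and 61, and without mice 74 and 81 452 and 140.

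The highest log2 fold changes also included Asb4, a ubiquitin ligase adaptor, 2.30-fold higher (SE of log2 0.24), Gimap5, a GTPase of lymphocytes, at 1.17 (SE 0.20), Srsf10 at 1.15 (SE 0.13), Cldn20 at 1.14 (SE 0.14), the noncoding Snhg14 at 1.12 (SE 0.26) and Gm3818 at 1.05 (SE 0.21). The lowest were those of Nagpa, an enzyme of lysosomal targeting, at -1.15 (SE 0.18), Tstd1 at -1.09 (SE 0.22), Dnase1l2 at -0.81 (SE 0.11), Gm5782 at -0.78 (SE 0.12), Cog8 at -0.65 (SE 0.11) and Smox, spermine oxidase, at -0.65 (SE 0.16). Gm3354 followed at -0.52, Stpg1, near background, at -0.49, Zfp791 at -0.48 and Scai at -0.45. For Scai 2 of 3 features, and for Smox 1 of 7, had the opposite sign. Of the genes in this paragraph, the call ended in some fits without 1 mouse for Asb4, Snhg14, Gm3818, Smox, Gm3354, Stpg1 and Zfp791, which passed in 23, 14, 22, 4, 15, 6 and 5 of 24.

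Of the 33 immediate early genes, 8 rose and 0 fell, or 12 and 1 when adjusted over the list alone. Maff was at 0.97, Dusp1 at 0.82, Btg2 at 0.76, Homer1, a postsynaptic scaffold gene, at 0.65, and Csrnp1 at 0.56; the last 3 were named after their values were seen, and 1 of 2 features of Homer1 had the opposite sign. The list passed camera (adjusted p = 7.56e-09), with adjusted p = 0.113 with an estimated correlation. Of 27 glucocorticoid-responsive genes 2 rose, Sgk1 and Dusp1, and 0 fell, against 2 and 1 when adjusted over the list alone. Fry without regard to direction gave this list an adjusted p of 3.26e-04, and 0.585 with direction. Clock rose by 0.39, Srsf5 by 0.34, Grik1 by 0.50, Tet3 by 0.34 and the histone acetyltransferase gene Kat2b by 0.55. Among cell type markers, Man1a, 1 of 9 for CA1 cells, rose by 0.68, and Olig2, 1 of 9 for oligodendrocyte precursors, by 0.27. Of 15 endothelial and pericyte markers 2 rose, Flt1 and Pecam1, by 0.48 and 0.47. None of these lists passed camera. Without 1 mouse, Homer1, Clock, Srsf5, Kat2b, Olig2 and Pecam1 passed in 7, 16, 5, 4, 14 and 17 of 24 fits. The choroid plexus markers were higher in 18 of 18 cases, at a median of 0.40, of 0.77 in the first slide pair and 0.21 in the second (camera adjusted p = 0.00328, and adjusted p = 0.645 with an estimated correlation). The other 28 lists had camera adjusted p from 0.112 to 0.983.

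Nr3c2 was at 0.77 (adjusted p = 0.0666) and did not pass, nor did Nr3c1 at 0.22, Cirbp at 0.40, Junb at 0.28, Arc at -0.11, Npas4 at 0.08, Fkbp5 at -0.12, Per1 at 0.10, Bdnf at 0.08, Crh at 0.13, Gria1 at 0.04, Grin1 at -0.25, Dnmt1 at 0.09, Dnmt3a at 0.19 or Ttr at 0.21. Without mouse 74 Fkbp5 was at 0.05, Grin1 at -0.03, Dnmt1 at 0.22, Gria1 at 0.11, Npas4 at 0.14, Bdnf at 0.03 and Crh at 0.07. Without mouse 81 Fkbp5 was at -0.20, Grin1 at -0.45 and Npas4 at 0.02, and without mouse 79 Dnmt3a was at 0.13. Nr3c2 passed without mouse 71 or 81 (adjusted p = 7.07e-04 and 0.0389). Ttr was at 0.67 with features averaged and did not pass. With features averaged Per1 passed at 0.62 (adjusted p = 8.94e-05) and Dnmt3a at 0.28 (adjusted p = 0.0252), Nr3c1 was at -0.03, Asb4 and Srsf10 passed at 0.74 and 0.61, and the call ended for Smox (-0.46), Zfp791 (-0.28), Scai (-0.01), Homer1 (0.26), Clock (0.43), Srsf5 (0.37), Kat2b (0.34) and Man1a (0.35). The count of 284 genes was 204 in the first slide pair, 1 in the second, 12 with cage and 124 with litter as a random block, 46 with time of sacrifice as a covariate and 592 without mice 74 and 81. Of the genes named in this comparison, those that passed with cage were Ccn1, Fos, Apold1, Srsf10, Cldn20, Dnase1l2, Dusp1 and Csrnp1. The count moved by over 1.5 times without mouse 61 (103), 62 (120), 63 (142), 69 (99), 70 (91), 71 (1465), 75 (78), 76 (140), 77 (132), 78 (163), 79 (98), 80 (121) or 81 (507).

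Both swum groups were compared with the same resting controls, and 40 genes rose and 12 fell in both comparisons. Independent lists of these sizes would share 0.464 and 0.034 genes. Lists of these sizes, taken by limma's moderated statistic from simulated unchanged groups with shared controls, had in common on average 12.7 genes at the upper and 2.91 at the lower end, and at most 19 and 8 in 100 simulations. That simulation drew every gene independently, so its highest values can understate overlap by chance. Such lists from the measured values with the resting controls split 4 and 4 had in common on average 25.2 and 7.44 genes. Over 100 splits they ranged from 14 to 37 and from 4 to 10. Across 26455 genes, which are not independent replicates, the log2 fold changes correlated at r = 0.532, against 0.50 in simulated unchanged groups with shared controls. Their covariance was 0.0205 against 0.0118 in the simulation. With the resting controls split 4 and 4, so that no control was shared, r averaged 0.295 over 100 splits and ranged from -0.155 to 0.578.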

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

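The tests on the choroid plexus markers and on mouse 74 were chosen only after the results were seen. A sample was singled out where its gap to the nearest other mouse of its group of 8 took up more of the group's range than Dixon's 95% critical value allows. This held in 25 of 207 groups of values, and chance gives about 1 in 20.

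Mouse 74 of the swum stressed lineage stood apart, with a mean correlation of 0.941 with its group against 0.979 for the nearest mouse. It was the only mouse analysed from its litter and from its cage, and the last killed on its day, so litter, cage and time cannot be told apart from it. A fault of a single array is argued against by its 2 arrays, whose deviations from the group correlated across genes at 0.949. Loss of particular transcripts, as in mouse 81 of the resting controls, is a candidate explanation. The deviations of both mice correlated across genes at 0.663. The other 191 pairs of mice from different groups ranged from -0.669 to 0.596, with a median of -0.003, so a high correlation alone does not single them out. Genes over 2 log2 units below the group numbered 1029 in mouse 74 and 322 in mouse 81, and 41 in mouse 69, the next highest. Kif5c was at 5.10 in mouse 74 and 5.29 in mouse 81, whereas Ndufv1 was at 6.68 and 13.12. Added tissue of another cell type cannot be told apart. The highest median deviation of a marker list, that of blood, was 0.51 with a spread of 0.65, too wide to decide. Replacement of most hippocampal tissue would lower hippocampal markers too, but medians were 0.00 for CA1, 0.06 for dentate granule and -0.08 for CA3 and CA2 markers. These values argue against such replacement behind the 1029 lowered genes. No biological explanation was tested.

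The mean of the choroid plexus markers was 11.15 in mouse 61 of the swum stressed lineage, against 9.08 for the nearest mouse. Group means were 8.67 ± 0.19 in resting controls, 9.32 ± 0.84 in swum controls and 9.20 ± 0.80 in the stressed lineage (SD, n = 8 each). Chance spread between mice cannot be told apart: the two-sided exact permutation p against resting controls was 0.0115 for swum controls and 0.00435 for the stressed lineage (0.0173 and 0.0131 adjusted over 3 comparisons), but this list was picked from 30 after its shift was seen, and fry gave adjusted p of 0.230 and 0.283. Differing carry-over of choroid plexus tissue is a candidate explanation, as the markers varied together within groups with a mean r of 0.704, a value close to the correlation of 0.706 already known from the list test. That value does not show what set the groups apart, and a response of the epithelium to the swim stays open and untested.

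Mouse 81 of the resting controls also had a mean correlation of 0.973 with its group, Srsf10 at 10.40, Grin1 at 11.99, Mcub at 10.24 and Fhdc1 at 7.48. Mouse 79 had Flt1 at 11.73 and Nagpa at 7.88, and mouse 80 had Arc at 12.84. Among swum controls, mouse 67 had Junb at 6.76, a median log2 value of 8.18 and a mean correlation of 0.988. In the stressed lineage, mouse 71 had Flt1 at 12.01, Nr3c2 at 7.14, Snhg14 at 6.97, Homer1 at 8.57, Kat2b at 9.63, Man1a at 9.28 and Pecam1 at 8.06, and mouse 74 had Fkbp5 at 10.63, Sgk1 at 11.01, Grin1 at 11.53, Dnmt1 at 7.85 and Smox at 9.33. All mice of this paragraph lay in the second slide pair. Mouse 61 was the only mouse of the first pair singled out by this rule.

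Other splits of the same mice, with 4 per group and slide pair, were tested 100 at a time, the real split included. For swum against resting controls, 1 of 100 splits, the real one, called as many as 80 genes, and the highest other called 2. For the stressed lineage against resting controls, 1 of 100 splits, again the real one, reached 284 genes, and the highest other called 21. These splits exchange single mice although cages lay within groups, and mice of a cage correlated at 0.196 by duplicateCorrelation. They therefore cannot exclude chance differences between cages, and with cage as a random block the counts were 18 and 12. Between the swum groups the real split called 0 genes, a count that 100 of 100 splits reach by construction, so the splits decide nothing there. Of the others 3 called any gene, with 152 at the highest, and whether the samples hold a structure other than lineage was not tested.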

How the results depend on the processing

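A fit within litters, leaving out mice 74 and 81, leaving out the stressed-lineage mice of the second slide pair, and, for named genes and lists, centring the arrays or repeating quantile normalization were chosen after the data were seen. For the 80 genes of the swim comparison and the 284 of the third, the counts were 51 and 164 with the first slide of each pair, 580 and 1225 with 48 arrays and mouse as random block, 34 and 125 without the slide pair term, 125 and 124 with litter and 18 and 12 with cage as random block, 52 and 46 with time of sacrifice, 264 and 89 with only the groups compared, 167 and 581 for every feature, 624 and 2198 with array weights, 27 and 39 at adjusted p under 0.01, 294 and 592 without mice 74 and 81, and 455 and 89 without the stressed-lineage mice of the second slide pair. Slide pair 2 alone gave 1 and 1, whereas slide pair 1, with as many mice, gave 173 and 204. The number of mice thus does not account for the difference between the pairs. Mean correlations with mice of the same group and slide were 0.9917 to 0.994 in the first pair and 0.9457 to 0.9738 in the second for the stressed lineage. They were 0.9934 to 0.9945 and 0.9734 to 0.9857 for resting controls, and 0.991 to 0.9919 and 0.9852 to 0.9901 for swum controls. The swim count alone moved to 53 with the second slides, 173 with slide pair 1, 172 with arrays centred, 133 with genes 1 log2 unit above background, 181 with genes above the median brightness, 142 with features averaged and 37 within the 3 litters shared by resting and swum controls, of which 7 were among the 80. Without single mice the swim count ranged from 36 to 241 and the third from 78 to 1465. The count between the swum groups was 0 in every alternative run, leave-one-out included. The fit with 48 arrays drew its degrees of freedom from arrays although groups differ only between mice, so its higher counts do not rest on more mice. Fewer mice or arrays and a stricter threshold are the construction of some of these settings. For the rest the cause was not tested.

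Called in 42 settings, which exclude single slide pairs, single features, the stricter p and the fit within litters, were 11 genes of the swim comparison, among them Fos, Apold1, Dusp1, Btg2, Csrnp1, Dnase1l2, Cog8, Dguok and Gm3354, and 7 of the third. A gene that a setting did not test counts as not called there, as with Ccn1 among genes above the median brightness; Ccn1 was called in the rest. Within litters 3 of the 11 and 5 of 26 called named genes passed. With cage as random block 14 of 26 called named genes of the swim comparison and 8 of 34 of the third passed. No called named gene changed sign in the alternatives run, whereas several that had not passed did. List medians stayed as given but lost the call with an estimated correlation for clock genes (0.0679), glutamate receptors (0.0717 after the swim, -0.0506 between lineages), choroid plexus (0.465 and 0.402), oligodendrocytes (0.0901 and -0.0391), astrocytes (-0.0481) and, in the third comparison, immediate early genes (0.168). Fry lost the same calls except those of clock and immediate early genes. Without mice 74 and 81 the call was lost for clock genes (0.0717), glutamate receptors after the swim (0.0391), oligodendrocytes after the swim (0.0997) and astrocytes between lineages (-0.0195), and with time of sacrifice for oligodendrocytes after the swim (0.0926). The correlation of the swim responses was 0.295 with split controls. The other value source was identical and gives no separate value. Genes within 1 log2 unit of background are limited by signal. The lineages shared no litter, so only resting and swum controls could be set against each other within litters.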

Other observations

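Growth hormone and prolactin were singled out after their spread was seen, whereas both tests here were set before their results were. Their transcripts differed widely between single mice in all groups. Gh ranged from 5.23 to 12.11 on the log2 scale with a median of 5.67, and Prl from 5.28 to 10.52 with a median of 5.92. Group means of Gh were 7.69 ± 2.38 in resting controls, 6.95 ± 1.87 in swum controls and 6.07 ± 1.21 in the stressed lineage (SD, n = 8 each). After group centring, Prl followed Gh across the 24 mice with r = 0.934 and rho = 0.918 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give, adjusted p = 8e-05 over 8 genes), and with r = 0.919 and 0.963 in the slide pairs. Without the 2 mice farthest from the median, r was 0.916.

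RNA of pituitary cells in some samples is a candidate explanation. Pomc and Cga, also abundant in the pituitary, correlated with Gh at a mean r of 0.626. For Pomc, which lay at least 1 log2 unit above background in all 24 mice, r was 0.641 and rho 0.570 (permutation p = 6.7e-04 and 0.0043, adjusted p = 0.0027), and 0.603 without the 2 farthest mice. For Cga, above that level in 1 mouse, r was 0.611 and rho 0.410 (permutation p = 0.0017 and 0.047, adjusted p = 0.0047), but 0.311 without those mice, so it rests on them. Within slide pairs r was 0.662 and 0.657 for Pomc and 0.637 and 0.664 for Cga, and rho was 0.643 and 0.413 for Pomc and 0.636 and 0.392 for Cga. Of the other pituitary genes, Pou1f1 was at r = 0.471 (adjusted p = 0.041), whereas Lhb, Fshb, Tshb and Pitx1, of which Tshb and Pitx1 lay at least 1 log2 unit above background in 24 mice, had r between -0.217 and 0.207 and did not pass, and expression within the hippocampus stays open. For Tshb the slide pairs differed, with r = -0.51 in the first and 0.56 in the second.

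A further hypothesis was that clock genes follow the time of sacrifice within groups. The mean absolute slope of the 17 clock genes was 0.0345 log2 units per hour, at percentile 37.9 of 10000 random lists matched on mean expression. The list as a whole thus showed no more trend than such lists. Within each group, cages were killed one after another, and mice of the first slide pair before those of the second. Time of sacrifice therefore ran largely with cage and slide pair. The slopes cannot separate these, so the percentile does not exclude a trend with time of day. For the time of sacrifice limma called 0 genes, with 1805 at an unadjusted p under 0.05. Dbp, at -0.10 per hour (SE 0.03), passed when adjusted over the list alone (adjusted p = 0.0226, and 0.576 over all genes), so a trend of this gene stays open. Ciart and Cry2 also had negative slopes and did not pass (adjusted p = 0.188 and 0.233 over the list alone).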
